A study of Mus musculus with 10 samples.

How the data were processed

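Binding of Dlx2, a homeodomain transcription factor of forebrain GABAergic neurons, was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in mouse brain tissue. Per the labels, 5 libraries are Dlx2 immunoprecipitations, from the basal ganglia, cortex and olfactory bulb at embryonic day 16 (E16) and from the cortex and olfactory bulb at postnatal day 3 (P3). The other 5 of the 10 samples are the matching input libraries, which were not analysed here. Each group has 1 immunoprecipitated library, so no comparison has replicates and no p-value is given between tissues or ages.

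The authors deposited a list of called regions per immunoprecipitated library in the narrowPeak layout of MACS2. Trimmomatic, Bowtie2, SAMtools and MACS2 are named, without versions, per the submitters' processing notes, as is the mouse genome build mm10. The peak-calling threshold, the control library used for each call and the read depth are not given in the sources used here. The fold enrichment of a region is the authors' ratio of signal at the summit over the local background, as MACS2 writes it. The authors' significance values are −log10 of the p-value and of the q-value at the summit, also written by MACS2. The deposited score column equals 10 times the −log10 q cut to a whole number in 14794 of 14795 regions of the E16 basal ganglia list and was not used further. Fold enrichment and −log10 q belong to a region in its own library and served only to describe and rank regions within a list. A strong region in a deeply sequenced library and in a shallow one can carry different values, and a longer list can hold weaker regions. The peak names carry a mark for removed duplicate reads in 4 of the 5 lists and in 0 of the 2139 regions of the P3 cortex list. Their naming pattern is shared by the E16 basal ganglia and E16 cortex lists, and another by the E16 olfactory bulb and P3 cortex lists, while the P3 olfactory bulb list has its own. No tissue and age was profiled under more than 1 pattern, so between lists of different patterns a batch and a group cannot be told apart.

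Each region held 1 summit, and no 2 regions of a list overlapped. No region was left out here for lying at a locus prone to artifact signal. Coordinates are those of mm10, counted from 1. Genes came from a RefSeq table of GRCm38.p6, the same build, with 49997 annotated genes, of which 21900 are protein-coding. The table gives the start and end of a gene but neither its strand nor its exons, and no genome sequence was used here. For this reason the plan made before the data were examined was followed with changes. Distance to either boundary of a gene replaced distance to the transcription start, gene body replaced exons and introns, random positions were drawn between the outermost features of a chromosome without masking unsequenced stretches, and the share of 18 fixed sequence motifs at summits was not computed.

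Regions of 2 lists were called shared when they overlapped by at least 1 bp, and shares carry exact Clopper-Pearson 95% intervals. For counts over all 5 lists, regions joined by such overlaps were merged, and a merged region can join regions that do not overlap each other. The overlap set by chance was taken from 1000 circular shifts of the other list along each chromosome. The intervals cover counting error only, not the variation between animals. Each overlap was also computed for the 734 regions highest in −log10 q of each list, which is the length of the shortest list. Genomic location was set beside 10 random positions per summit on the same chromosome. A gene was counted as occupied when a summit lay within its body extended by 10 kb on each side. For each of 17 gene lists fixed before the data were examined, with 257 genes that were all found in the table, the number of occupied members was ranked among 10000 random lists of protein-coding genes matched on length in 20 bins. Ties were shared equally between above and below. A percentile of at least 95 is called high here, which describes these libraries and is not a test between them. The lists were the Dlx family, GABA synthesis and transport, ganglionic eminence and GABAergic lineage transcription factors, striatal projection neuron genes, olfactory bulb interneuron genes, cortical interneuron subtype genes, chemokine and migration genes, synapse genes, cell survival and apoptosis genes, Notch and neurogenesis genes, cortical glutamatergic lineage genes, and ubiquitous genes. Markers of oligodendrocytes, astrocytes, microglia, endothelial and mural cells, and of liver and muscle stood for other cell types. Some genes belong to more than 1 list, so the lists are not independent.

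The rule for named genes was fixed before the data were examined. It takes Cxcl14, Dlx1, Dlx2, Dlx5 and Dlx6 in every list, the gene at the 10 regions highest in −log10 q of each list, the gene at the 5 highest regions missing from the other list of a comparison, the gene at the 10 shared regions with the lowest summed rank, and up to 4 members of each gene list with the strongest summits. The gene at a region is the shortest protein-coding gene whose body holds the summit, or otherwise the protein-coding gene with the nearest boundary. A region assigned this way need not act on that gene. A gene named for a region in this way can lie at any distance, such as 632 kb for a region near Tle4. Some genes that the rule takes are not reported here. Small nuclear and nucleolar RNA genes, the examples of regions in all 5 lists, and Sst, Ackr3, Cxcr4, Cxcl12 and other list members outside the rule were chosen after their values were seen.

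Alternatives were a −log10 q of at least 5 or 10, overlap of at least 50% of both regions, summits at most 200 bp apart, equal list lengths, numbered chromosomes and X only, a boundary distance of 2500 bp, protein-coding genes only, gene bodies extended by 50 kb, a window of 5 kb around gene boundaries and a window of 500 kb around Cxcl14. Leaving out regions wider than 1 kb, the E16 cortex list or the P3 cortex list was added after seeing the data. The scripts were tested on simulated data. With 500 regions of the E16 olfactory bulb list planted in a shifted copy, 500 were recovered. Of 200 random lists of 20 genes, 10 reached the percentile of 95 on the E16 olfactory bulb occupancy, and 100 of 100 lists with 6 planted occupied genes did. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.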

Results

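Dlx1 and Dlx2 are homeodomain transcription factors needed for the development and survival of forebrain GABAergic neurons, and the series asks where Dlx2 binds in the genome across brain regions and ages, with the chemokine gene Cxcl14 as a proposed direct target. The data are 5 lists of Dlx2-enriched regions, 1 per tissue and age. The E16 basal ganglia, where most cortical and olfactory interneurons arise, gave 14795 regions covering 10469 kb. The E16 cortex gave 6333 regions covering 5935 kb and the E16 olfactory bulb 1666 covering 737 kb. At P3 the olfactory bulb gave 734 regions covering 327 kb and the cortex 2139 covering 974 kb. These include 1 mitochondrial region in the P3 bulb list and 3 in the P3 cortex list. The widest P3 bulb region spanned 16299 bp and need not be a nuclear one. The mitochondrial region of that list was over 1 kb wide, and 4 of its 5 regions of that width remained without it. The share of wide regions given below counts it as well. Read depth is unknown, so a region missing from a list was below the authors' threshold in that library and is not shown to be unbound.

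The strongest regions differed in kind between the lists. In the E16 basal ganglia list they lay within Pou3f3, a POU-domain transcription factor gene (fold enrichment 55.7), within Mex3a and Mex3b, which encode RNA-binding proteins (53.2 and 44.5), near Polg, the mitochondrial DNA polymerase gene (46.8), and within Mn1 (46.1), Zfp316 (41.2), Marcks (40.5) and Fam171a2 (39.9). The strongest E16 cortex regions were largely assigned to the same genes, with Mex3a (71.9), Fam171a2 (64.3), Pou3f3 (63.2), Polg (63.0) and Zfp316 (62.8). The protocadherin gene Dchs1 had 59.1 and the kinase gene Mast1 47.9. These regions were wide. That near Polg, with its summit 47.7 kb outside the gene, spanned 19000 bp in the basal ganglia and 27627 bp in the cortex. Regions over 1 kb made up 13.8% of the E16 basal ganglia list (95% interval 13.3 to 14.4) and 25.2% of the E16 cortex list (24.1 to 26.3), against 0.36% (0.132 to 0.782), 0.681% (0.222 to 1.58) and 1.92% (1.38 to 2.59) of the E16 bulb, P3 bulb and P3 cortex lists. The median width was 501, 571, 413, 383 and 395 bp in the same order.

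The E16 olfactory bulb list was led by a region of 879 bp located 42.1 kb outside Sema6a, a semaphorin gene (fold enrichment 20.5, chromosome 18, 47412913 to 47413791). It was followed by regions near Acadsb (18.0), Dph6 (17.0), Eapp (16.2) and Dlx6 (15.2), near the LIM-domain gene Lmo1 (12.5), and within Adk, the adenosine kinase gene (11.5), Pard3b (14.5), Otud7a (11.5) and the TGF-beta signalling gene Smad2 (12.1). In the P3 olfactory bulb the leading regions lay within Tex14 (14.7 and 17.1), near Acadsb (18.1), Nectin1 (14.3), Arl4d (13.02), Igdcc3 (16.2), Gapt (8.47) and Rdm1 (11.2), and within Lrmda (13.6). Those within Tex14 and near Arl4d sat at annotated small nuclear or nucleolar RNA genes. The P3 cortex list was led by the Sema6a (47.5) and Smad2 (49.1) regions, then by regions near Sowahb (39.3) and Arrdc4 (23.7) and within Grip1 (43.5), Slc38a9 (39.7), Fbxl13 (25.4), Kcnk1 (31.9) and Zbtb4 (30.1).

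The basal ganglia and cortex at E16 shared their strongest regions. Of the 100 strongest E16 cortex regions, 99 overlapped a basal ganglia region (95% interval 94.6 to 99.97%), and 96 of the 100 strongest basal ganglia regions overlapped a cortex region (90.1 to 98.9%). The shared regions with the lowest summed rank lay within Pou3f3, Mex3a, Fam171a2, Zfp316, Mex3b, Dchs1 and the semaphorin gene Sema6c and near Polg. Over the whole lists, 3894 of 6333 cortex regions (61.5%, 60.3 to 62.7) overlapped a basal ganglia region, where shifted lists gave a mean of 61.1 and a maximum of 202. The cortex regions missing from the basal ganglia list were led by a region 368 kb from the chromatin remodelling gene Arid1b (fold enrichment 39.2), followed by regions within Emx1, a homeobox gene of the cortical primordium (19.7), Brd1 (18.4) and the interferon receptor gene Ifnar1 (15.8). The Emx1 region covered 6279 bp of chromosome 6, from 85189217 to 85195495. In the other direction, the basal ganglia regions missing from the cortex list were led by regions near Acadsb (25.6), Psat1 (23.3), Ccdc39 (22.3) and Fign (24.8) and within Nubpl (24.0), and each of these was in the E16 olfactory bulb list. The shared part was wider, with a median cortex region of 754.5 bp against 430 bp for those not shared. The share was 35.4% when the 734 strongest regions of each list were used and 35.5% without regions wider than 1 kb.

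Most E16 olfactory bulb regions were also basal ganglia regions. Of 1666 bulb regions, 1212 overlapped the basal ganglia list (72.7%, 70.5 to 74.9), against a mean of 11.2 and a maximum of 23 in shifted lists. The shared regions with the lowest summed rank lay near Dlx6, Lmo1, Acadsb, Tle4 and the potassium channel gene Kcnn2 and within Adk, the neurodevelopmental gene Auts2 and Shtn1. In the basal ganglia list the fold enrichment was 36.0 within Auts2, 35.6 near Dlx6, 34.0 within Shtn1 and 32.5 within Adk. It was 26.1 for the region 145 kb from Kcnn2, 25.2 for that 207 kb from Tle4 and 19.96 for that 16.4 kb from Lmo1. Basal ganglia regions shared with the bulb had a median fold enrichment of 8.35, against 4.49 for those not shared. Bulb regions missing from the basal ganglia list were led by those near Sema6a and within Smad2, Grip1 (12.3) and Tex14 (10.2). Tbx21, a T-box gene of olfactory bulb projection neurons, also held such a region (10.8). The Tex14 region sat at the small nuclear or nucleolar RNA gene Rnu3b4. The basal ganglia regions missing from the bulb list were led by Mex3a, Polg, Marcks and Mn1. With 734 regions per list the shared part was 30.1% (26.8 to 33.6).

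The E16 bulb and E16 cortex lists shared few regions, although the strongest bulb regions were shared more often. They shared 142 of the 1666 bulb regions (8.52%, 7.23 to 9.97), against a mean of 5.79 and a maximum of 16 in shifted lists. Of the 100 strongest bulb regions, 25 overlapped a cortex region (16.9 to 34.7%). In the other direction, 2 of the 100 strongest cortex regions overlapped a bulb region (0.243 to 7.04%). Shared regions with the lowest summed rank lay, with the fold enrichment in the cortex list, within Apc2 (28.4), Auts2 (9.73), Shtn1 (8.89), the zinc finger gene Zeb2 (13.9), Arhgap15 (8.46), Pou3f3 (63.2), the phosphatase gene Ptprs (18.7), the basic helix-loop-helix gene Tcf4 (9.76) and Gse1 (10.4), and near Dlx6 (8.67). These places are those of the cortex summits. At Pou3f3 and Ptprs the bulb region met only the edge of the cortex region, with a fold enrichment of 4.43 and 4.46. The bulb summit at Pou3f3 lay outside the gene (42695566). Bulb regions missing from the cortex list were led by Sema6a, Acadsb, Eapp, Pard3b and Otud7a. Cortex regions missing from the bulb list were led by Mex3a, Polg, Fam171a2 and Zfp316. Of the 734 strongest regions of each list, 4 were shared (0.545%, 0.149 to 1.39), where shifted lists reached up to 5.

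**Figure D1:**
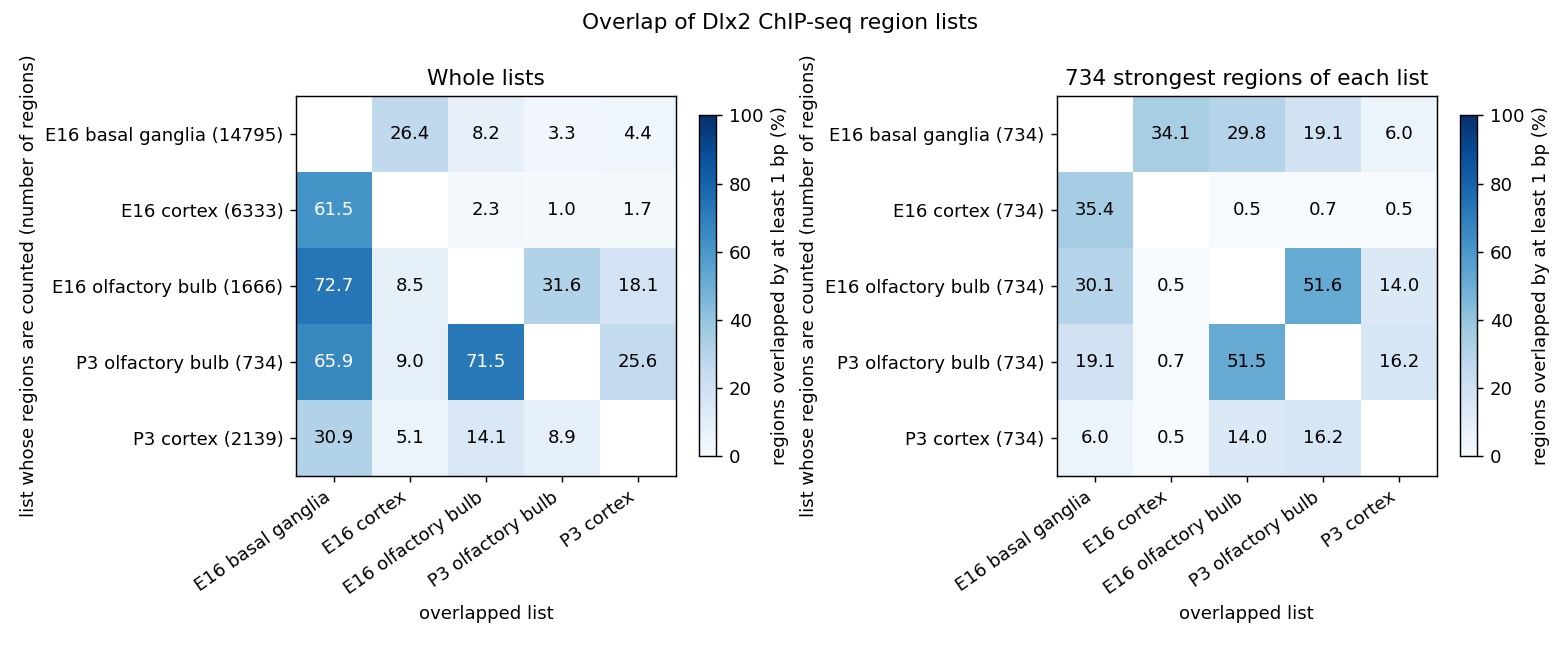
Percentage of the regions of each list (rows, with the number of regions) that overlap a region of another list (columns) by at least 1 bp, for whole lists on the left and the 734 strongest regions of each list on the right. The E16 and P3 olfactory bulb lists overlapped most at equal length (51.5% of P3 regions), and the E16 cortex list overlapped the basal ganglia list (35.4%) but hardly any other.

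Across age, the cortex lists differed in their leading genes. Only 110 of 2139 P3 cortex regions overlapped an E16 cortex region (5.14%, 4.25 to 6.17), above the shifted mean of 7.24 and maximum of 17. The shared regions with the lowest summed rank lay near Mef2c, a MADS-box transcription factor gene (fold enrichment 23.2 at E16 and 11.2 at P3), near the ammonium transporter gene Rhcg (25.5 and 12.3, and 31.6 and 4.23), Dlx6 (8.67 and 9.20), Lmo1 (7.44 and 11.6) and Esp38 (1.83 and 1.78), and within Auts2 (9.73 and 7.91), Mtss1 (8.89 and 5.47), Ptprs (18.7 and 4.51) and Tcf4 (10.4 and 4.90). By their E16 summits, these regions lay 70.9 kb from Mef2c, 49.9 and 61.5 kb from Rhcg and 103 kb from Esp38. The Esp38 region was below the median fold enrichment of both lists (5.02 at E16 and 4.42 at P3), and artifact signal there stays open. A pair could join different summits. The E16 and P3 summits were 83737997 and 83741710 near Mef2c, and 79531854 and 79535556 for the second Rhcg pair. Those within Ptprs and Tcf4 and near Dlx6 were also more than 200 bp apart. P3 regions missing from the E16 list were led by Sema6a, Smad2, Sowahb, Grip1 and Slc38a9, all of which were in both olfactory bulb lists. E16 regions missing from the P3 list were led by Mex3a, Pou3f3, Polg, Fam171a2 and Zfp316. The 734 strongest regions of each list shared 4 (0.545%, 0.149 to 1.39), where shifted lists gave up to 5. Age is not the only difference between these libraries, since their peak names follow different patterns and only the E16 names mark removed duplicates.

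In the olfactory bulb, by contrast, most P3 regions were already listed at E16. The lists shared 525 of the 734 P3 regions (71.5%, 68.1 to 74.8), with a mean of 0.439 and a maximum of 4 in shifted lists. At P3 the fold enrichment of the leading shared regions was 18.1 near Acadsb, 13.5 within the transporter gene Abcb1a, 13.4 near Dlx6, 12.6 near Lmo1, 11.8 near Sema6a, 11.7 near Eapp, 11.1 within Adk, 10.4 within Otud7a and 9.35 within the homeobox gene Pbx3. A region 67.3 kb outside Smad2 was also among them (13.1). P3 regions missing from the E16 list were led by Igdcc3 (16.2), Sec22c (11.5), Col19a1 (2.14), Myo3a (2.63) and Ctif (8.12). The region near Col19a1 was wide, at 4786 bp, and its summit lay 25.1 kb outside the gene. It and the Myo3a region ranked high by −log10 q but lay below the list's median fold enrichment of 5.69. Since no locus prone to artifact signal was left out, such signal at these regions stays open. E16 regions missing from the P3 list were led by Plekha6 (12.5), Bbs9 (11.7), Naa11 (10.7), the homeobox gene Msx2 (11.0, with the summit 0.18 kb from the gene) and Ak8 (10.8). With 734 regions per list, 378 were shared (51.5%, 47.8 to 55.2). The difference between the cortex share of 5.14% and the bulb share of 71.5% rests on 1 library per group and was not tested against the spread between animals.

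The P3 cortex and P3 bulb lists shared 188 of the 734 bulb regions (25.6%, 22.5 to 28.9), against a mean of 1.62 and a maximum of 6 in shifted lists. Shared regions with the lowest summed rank lay near Sema6a, Sowahb, Arl4d, Rdm1 and Taf12 and within Slc38a9, Tex14 and Grip1. In the bulb list their fold enrichment was 11.8 near Sema6a, 13.3 near Sowahb, 13.02 near Arl4d and 10.2 near Taf12. It was 11.6 within Slc38a9 and 11.6 within Grip1. The regions within Tex14 and near Arl4d and Taf12 sat at small nuclear or nucleolar RNA genes. All 31 P3 bulb regions within 1 kb of a small nuclear RNA gene were in the P3 cortex list. Bulb regions missing from the cortex list were led by Acadsb (18.1) and Nectin1 (14.3) and by regions within the sodium leak channel gene Nalcn (15.0), the G protein gene Gnao1 (12.5) and Fam171b (14.5), and all 5 were in the E16 basal ganglia and E16 bulb lists. Cortex regions missing from the bulb list were led by Arrdc4 (23.7), Fbxl13 (25.4), Btbd3 (26.7) and Cetn3 (19.0), those at Btbd3 and Cetn3 lying 549 and 711 kb from the gene.

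The 5 lists merged into 18667 regions, of which 13601 were in 1 list, 4377 in 2, 527 in 3, 128 in 4 and 34 in all 5. Those in all 5 included regions flanking Dlx6, regions near Lmo1, Tle4, Foxp1, Kcnn2, Kcng1 and Pbx3, and regions within Auts2, Shtn1, Zeb2, Adk, Spon1, Lrmda, Dscaml1, Syt9 and the nociceptin precursor gene Pnoc. In the E16 bulb list their fold enrichment was 15.2 and 8.76 near Dlx6, 12.9 within Auts2, 12.5 near Lmo1 and 11.5 near Foxp1. It was 3.93 within Pnoc. By their E16 bulb summits, these regions lay 16.3 kb from Lmo1, 207 and 632 kb from Tle4, and 157 kb from Foxp1. Those near Kcnn2, Kcng1 and Pbx3 lay 145, 62.4 and 64.1 kb away. Of the merged regions, 65.8% of those in the basal ganglia list (65.0 to 66.6) and 64.3% of those in the P3 cortex list (62.2 to 66.4) were in no other list, against 41.7% for the E16 cortex, 18.4% for the E16 bulb and 13.8% for the P3 bulb. Counted from the P3 bulb list, 33 regions were in all 5 lists, 96 were in all lists when the E16 cortex was left out, and 61 when the P3 cortex was left out.

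The E16 cortex regions lay almost entirely at genes. Of their summits, 21.9% were within 1 kb of a gene boundary (20.9 to 22.9), a further 73.1% lay elsewhere within a gene (71.9 to 74.1), and 5.05% were outside genes (4.53 to 5.62), where random positions gave 48.8% outside genes. In the E16 basal ganglia 16.7% were at a boundary (16.1 to 17.3) and 23.6% outside genes (22.9 to 24.3). The E16 bulb had 10.9% at a boundary (9.47 to 12.5) and 39.4% outside genes (37.1 to 41.8), the P3 bulb 15.4% (12.9 to 18.2) and 35.1% (31.6 to 38.6), and the P3 cortex 18.2% (16.6 to 19.9) and 35.7% (33.6 to 37.7). Random positions fell within 1 kb of a boundary in 6.41%, 6.51%, 6.55%, 6.67% and 6.18% of cases for the E16 basal ganglia, E16 cortex, E16 bulb, P3 bulb and P3 cortex. The boundary shares were lower with protein-coding genes alone, at 10.9%, 16.3%, 5.40%, 8.46% and 12.1% in that order.

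**Figure D2:**
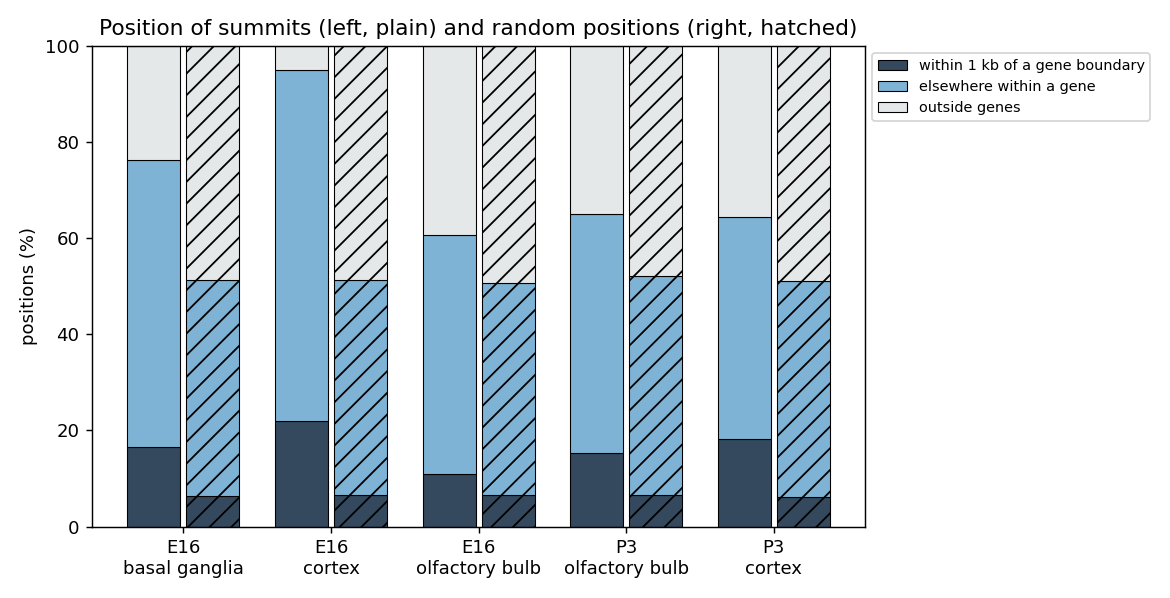
Percentage of summits (plain bars, left) and of random positions on the same chromosomes (hatched bars, right) within 1 kb of a gene boundary, elsewhere within a gene and outside genes, for each list. Summits outside genes made up 5.05% of the E16 cortex list and between 23.6% and 39.4% of the other lists.

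Genes that encode the GABAergic lineage program were occupied far more often than length-matched random genes in most lists. In the E16 basal ganglia and E16 cortex lists the same held for ubiquitous genes (percentile 99.9 in both). Of 28 ganglionic eminence and GABAergic lineage transcription factors, 25 were occupied in the E16 basal ganglia (percentile 100), 13 in the E16 cortex (99.95), 11 in the E16 bulb (100), 6 in the P3 bulb (99.9, and 92.8 within 5 kb of gene boundaries) and 8 in the P3 cortex (99.7). The strongest members in the basal ganglia included Sp9 (fold enrichment 36.5) and Nr2f1 (25.6), and those in the E16 cortex Nr2f1 (48.7), Meis2 (20.4) and Sp9 (16.5). The bulb lists had other leading members, among them Pbx3 (12.4), Sox6 (8.20) and Zfhx3 (6.24) at E16 and Pbx3 (9.35), Npas1 (7.18) and Sox6 (6.83) at P3. In the P3 cortex Pbx3 (8.30), Npas3 (5.77) and Zeb2 (3.82) were among the strongest. Genes for GABA synthesis and transport were occupied in 5 of 7 cases in the basal ganglia (percentile 98.6), with Slc32a1, the vesicular GABA transporter gene (33.0), Gad1 (17.7) and Gad2 (16.6) among them. The E16 cortex had 4 (98.6), the E16 bulb 4 (99.995) and the P3 bulb 3 (100), and each included Gad1 and Gad2. In the P3 cortex the only member was Slc6a11 (percentile 75.04). The percentile of this list in the E16 cortex was 86.3 with 734 regions per list and 92.9 with gene bodies extended by 50 kb.

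Genes of neuronal progenitors and of glutamatergic neurons were also occupied in the E16 basal ganglia and cortex lists, and so were ubiquitous genes. Of 20 cortical glutamatergic lineage genes, 17 were occupied in the E16 cortex (percentile 100), including Neurod2 (49.1), Tbr1 (48.5) and Lhx2 (33.1), and 15 in the basal ganglia (99.99), where Tbr1 had 11.1. The bulb had 4 at E16 (98.9) and 3 at P3 (98.7), with Tbx21 (10.8 and 8.12) and Cux1 (5.11 and 8.22) in both, and the P3 cortex had 1 (28.7). These bulb percentiles passed below 95 under some alternatives: at E16 they were 92.0 at a −log10 q of at least 10, 88.8 within 5 kb of gene boundaries and 93.7 with 734 regions per list, and at P3 94.7 within 5 kb and 94.6 with gene bodies extended by 50 kb. Notch and neurogenesis genes were occupied in 12 of 15 cases in the basal ganglia and in 10 in the E16 cortex (percentile 100 in both), with Sox1 (22.2 and 28.0), Sox2 (22.0 and 13.5), Sox4 (18.0 and 18.9) and Sox11 (12.3 and 23.2). The E16 bulb held Sox1, Notch1 and Sox4 (99.9), but its percentile was 44.5 at a −log10 q of at least 10 and 45.2 with 734 regions per list. The P3 cortex held Sox4 and Notch2 (94.3, and 96.4 at a −log10 q of at least 5), and the P3 bulb 0 of 15. Ubiquitous genes, which served as a control, were occupied in 8 of 12 cases in both the E16 basal ganglia (percentile 99.9) and the E16 cortex (99.9), including Tubb5 (17.0 and 24.3), Gapdh (18.2 and 27.1) and Rpl13a (12.3 and 21.4), with 94.9 in the basal ganglia when gene bodies were extended by 50 kb. None of the 12 was occupied in the E16 bulb, P3 bulb or P3 cortex lists (percentiles 41.6, 44.6 and 32.2). Random lists were matched on length only. In the E16 basal ganglia and E16 cortex lists, a high percentile alone thus does not set a gene list apart from ubiquitous genes.

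Migration genes were high in the E16 basal ganglia and both bulb lists, and synapse genes in the E16 basal ganglia and E16 cortex lists. Chemokine and migration genes were occupied in 19 of 23 cases in the basal ganglia (percentile 99.9), led by Epha4 (19.7), Efna5 (16.5), Cdk5r1 (15.6) and Slit1 (13.5), in 12 in the E16 bulb (100) and in 7 in the P3 bulb (99.9), where Erbb4 (11.6 and 11.1), Gfra1 (10.8 and 7.64) and Efna5 (7.38 and 7.49) led. The E16 cortex had 5 (53.0) and the P3 cortex 7 (88.3), with Robo2 at 10.3 and Erbb4 at 9.15. Within 5 kb of gene boundaries 0 of these genes were occupied in either bulb list (percentiles 35.02 and 44.2), so these counts came from summits farther from the gene boundaries. Synapse genes were occupied in 19 of 28 cases in the basal ganglia (96.8), led by the neurexin genes Nrxn2 (31.2) and Nrxn3 (19.0) and by Nlgn2 (16.6), and in 11 in the E16 cortex (98.8), led by Nrxn2 (36.3), Shank1 (20.4) and Shank3 (13.99). With gene bodies extended by 50 kb neither stayed high (86.0 and 90.1), and at a −log10 q of at least 5 the basal ganglia percentile was 93.2. The E16 bulb had 4 (42.3), the P3 bulb 3 (69.9) and the P3 cortex 7 (78.1). Cell survival and apoptosis genes were occupied in 9 of 18 cases in the basal ganglia (95.3), led by Pcdhga1 (16.02), Akt1 (11.1) and Bdnf (9.20), but the percentile was 71.1 with 734 regions per list and 86.5 at a −log10 q of at least 10. In the other lists 5 (83.9, E16 cortex, and 96.9 within 5 kb of gene boundaries), 1 (58.8, E16 bulb, Bdnf), 0 (30.0, P3 bulb) and 2 (71.6, P3 cortex) were occupied.

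Among the neuron subtype lists, olfactory bulb interneuron genes were occupied in 15 of 17 cases in the E16 basal ganglia (percentile 100), led by Sp9 (36.5), Pbx3 (22.7), Meis2 (17.5) and Tiam2 (15.4). The E16 bulb had 4 (98.1), which were Pbx3 (12.4), Th, the dopamine-synthesis enzyme gene (5.93), Sp9 (4.18) and Meis2 (3.59), the E16 cortex 6 (94.0), the P3 bulb 2 (90.2) and the P3 cortex 2 (54.1). The E16 cortex percentile rose to 95.8 and 99.5 at a −log10 q of at least 5 and 10, 99.6 within 5 kb of gene boundaries, 99.96 with 734 regions per list and 96.8 without regions wider than 1 kb. That of the E16 bulb fell to 88.9 at a −log10 q of at least 10 and 90.6 with 734 regions per list. Sp9, Pbx3 and Meis2 are also among the ganglionic eminence and GABAergic lineage transcription factors, so their occupancy counts in both lists. Striatal projection neuron genes were occupied in 11 of 19 cases in the basal ganglia (94.9), with Bcl11b (25.4), Foxp1 (20.3), the opioid receptor gene Oprm1 (15.6) and Foxp2 (15.2), and in 6 in the E16 bulb (99.8), with Foxp2 (6.95) and Oprm1 (6.75). The basal ganglia reached 99.2 with 734 regions per list and 96.8 without regions wider than 1 kb, and the E16 bulb fell to 85.7 with 734 regions and 88.0 within 5 kb of gene boundaries. The E16 cortex had 4 (55.2), the P3 bulb 1 (55.8, Oprm1) and the P3 cortex 1 (16.2, Ppp1r1b). Cortical interneuron subtype genes did not stand out, with 5 of 20 occupied in the basal ganglia (44.0), led by Htr3a (13.3), Elfn1 (11.1), Npy (9.57) and Reln (7.62), 2 in the E16 cortex (17.5), 2 in the E16 bulb (93.3), 1 in the P3 bulb (82.2) and 1 in the P3 cortex (49.4). The somatostatin gene Sst had 0 summits within 10 kb in any list.

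Markers of other cell types did not reach the percentile of 95 in any list in the main setting. Oligodendrocyte lineage genes were occupied in 3 of 12 cases in the basal ganglia (52.2), with Olig2 at 8.79, in 1 in the E16 cortex (21.6) and in 0 in the E16 bulb, P3 bulb and P3 cortex (37.3, 41.6 and 27.0). Astrocyte genes were occupied in 3 of 10 cases in the basal ganglia (44.1), with Nfia at 15.0, 2 in the E16 cortex (54.1), 1 in the E16 bulb (72.4), 1 in the P3 bulb (84.7) and 2 in the P3 cortex (88.5). They did reach it with 734 regions per list in the basal ganglia (99.7) and E16 cortex (95.1), and with gene bodies extended by 50 kb in the P3 cortex (97.2). Microglia genes had 3 of 10 (60.4), 1 (27.2), 0 (38.7), 0 (42.4) and 1 (74.6) in the same order of lists. Endothelial and mural genes had 1 of 10 (10.9), 1 (33.8), 0 (33.2), 0 (39.2) and 1 (66.2), and liver and muscle genes 1 of 12 (11.8), 1 (21.8), 0 (40.6), 0 (44.1) and 0 (32.1). Of the 85 combinations of a gene list and a region list, 32 reached the percentile of 95. Of these, 18 did so under every alternative that was run. Because some gene lists share members, the combinations are not independent.

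**Figure D3:**
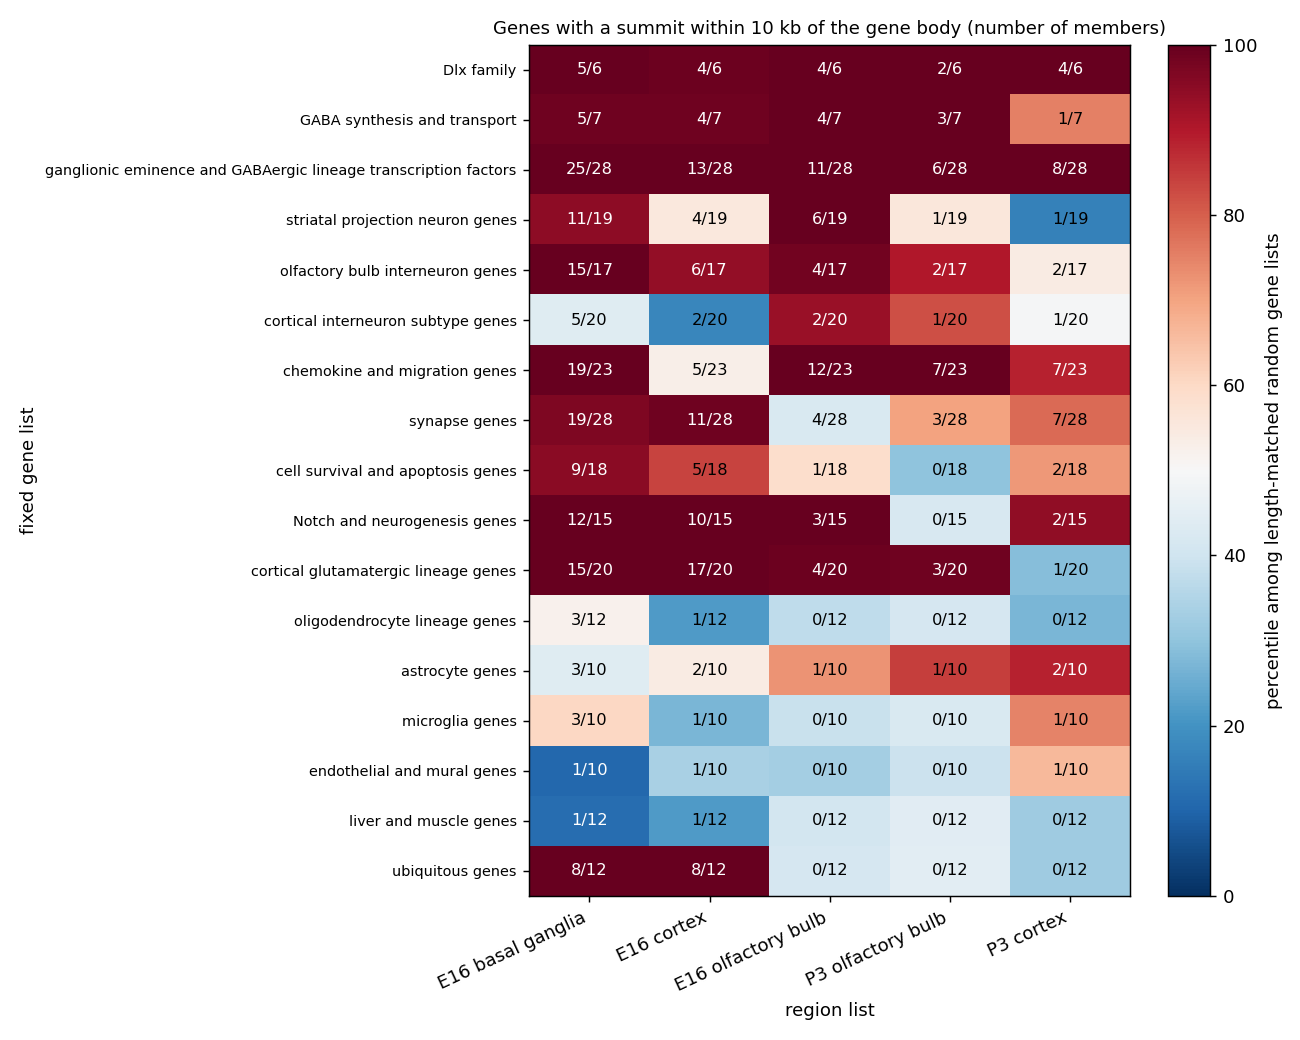
Number of members of each fixed gene list with a summit within 10 kb of the gene body, out of all members, with the color giving the percentile among length-matched random gene lists (0 to 100). The Dlx family and the ganglionic eminence transcription factors are high in all 5 region lists, and ubiquitous genes are high in the E16 basal ganglia and E16 cortex lists (8 of 12 each).

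Dlx genes carried regions in every list. They form neighbouring pairs, so that a summit can count for both genes of a pair. The Dlx family list was high in all 5 region lists, with 5 of 6 genes occupied in the basal ganglia (percentile 99.8), 4 in the E16 cortex (99.0, and 92.4 with gene bodies extended by 50 kb), 4 in the E16 bulb (100), 2 in the P3 bulb (99.9) and 4 in the P3 cortex (99.995). At Dlx1 (chromosome 2, 71528113 to 71533981) and Dlx2 (71543408 to 71546754) the basal ganglia list had 17 summits within 100 kb. The strongest covered Dlx2 (71540119 to 71546773, fold enrichment 35.3), and others lay 10.5 kb outside Dlx1 (27.6), between the genes (22.8 and 16.9) and at the Dlx1 boundary (13.4). The E16 cortex had 8 summits there, with 12.8 within Dlx2, and the E16 bulb 5, led by an intergenic region at 71535891 to 71536580 (10.6). The P3 cortex had 5, led by 71537795 to 71538529 (6.68). The P3 bulb had 0 within 100 kb of either gene, and its nearest summit lay 880 kb from Dlx2.

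At Dlx6 (chromosome 6, 6863334 to 6867970) and Dlx5 (6877801 to 6882068) every list had regions. In the basal ganglia a region of 13007 bp between these genes and over part of Dlx5 (6868297 to 6881303) had a fold enrichment of 35.6, with its summit 1.68 kb outside Dlx6. The same site was listed in the E16 bulb (6869067 to 6870052, 15.2), the P3 bulb (6869234 to 6869927, 13.4), the E16 cortex (6869298 to 6869978, 6.59) and the P3 cortex (6869305 to 6869952, 5.02). A site on the other side of Dlx6, with its summit at 6861956 in the E16 bulb (8.76), had 23.0 in the basal ganglia, 5.17 in the P3 bulb and 9.20 in the P3 cortex. In the E16 cortex the edge of a region with its summit at 6860278 overlapped it (6859797 to 6861788, 8.67).

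Cxcl14 (chromosome 13, 56288643 to 56296811), a chemokine gene, had 0 summits within 10 kb in any list. Within 100 kb the E16 basal ganglia list had 2 summits, 66.6 kb from the gene (56221960 to 56222275, fold enrichment 4.12) and 91.4 kb from it on the other side (56388012 to 56388455, 6.45). The E16 cortex had 1, at 57.5 kb (56230857 to 56231156, 3.91), with a −log10 q of 3.70. The E16 bulb, P3 bulb and P3 cortex had 0 within 100 kb. Their nearest summits coincided 305 kb from the gene, at 56602300, 56602266 and 56602280, with a fold enrichment of 4.76, 7.25 and 24.9. A summit within 100 kb was common in the longer lists: among 21631 protein-coding genes, 55.8% had at least 1 in the basal ganglia list, 38.0% in the E16 cortex, 10.8% in the E16 bulb, 6.20% in the P3 bulb and 19.2% in the P3 cortex. Among other chemokine genes of the fixed list, Ackr3 had 4 summits within 10 kb in the basal ganglia (12.4), Cxcr4 had 1 in the basal ganglia (3.10) and 1 in the P3 cortex (4.12), and Cxcl12 had 0 in any list.

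**Figure D4:**
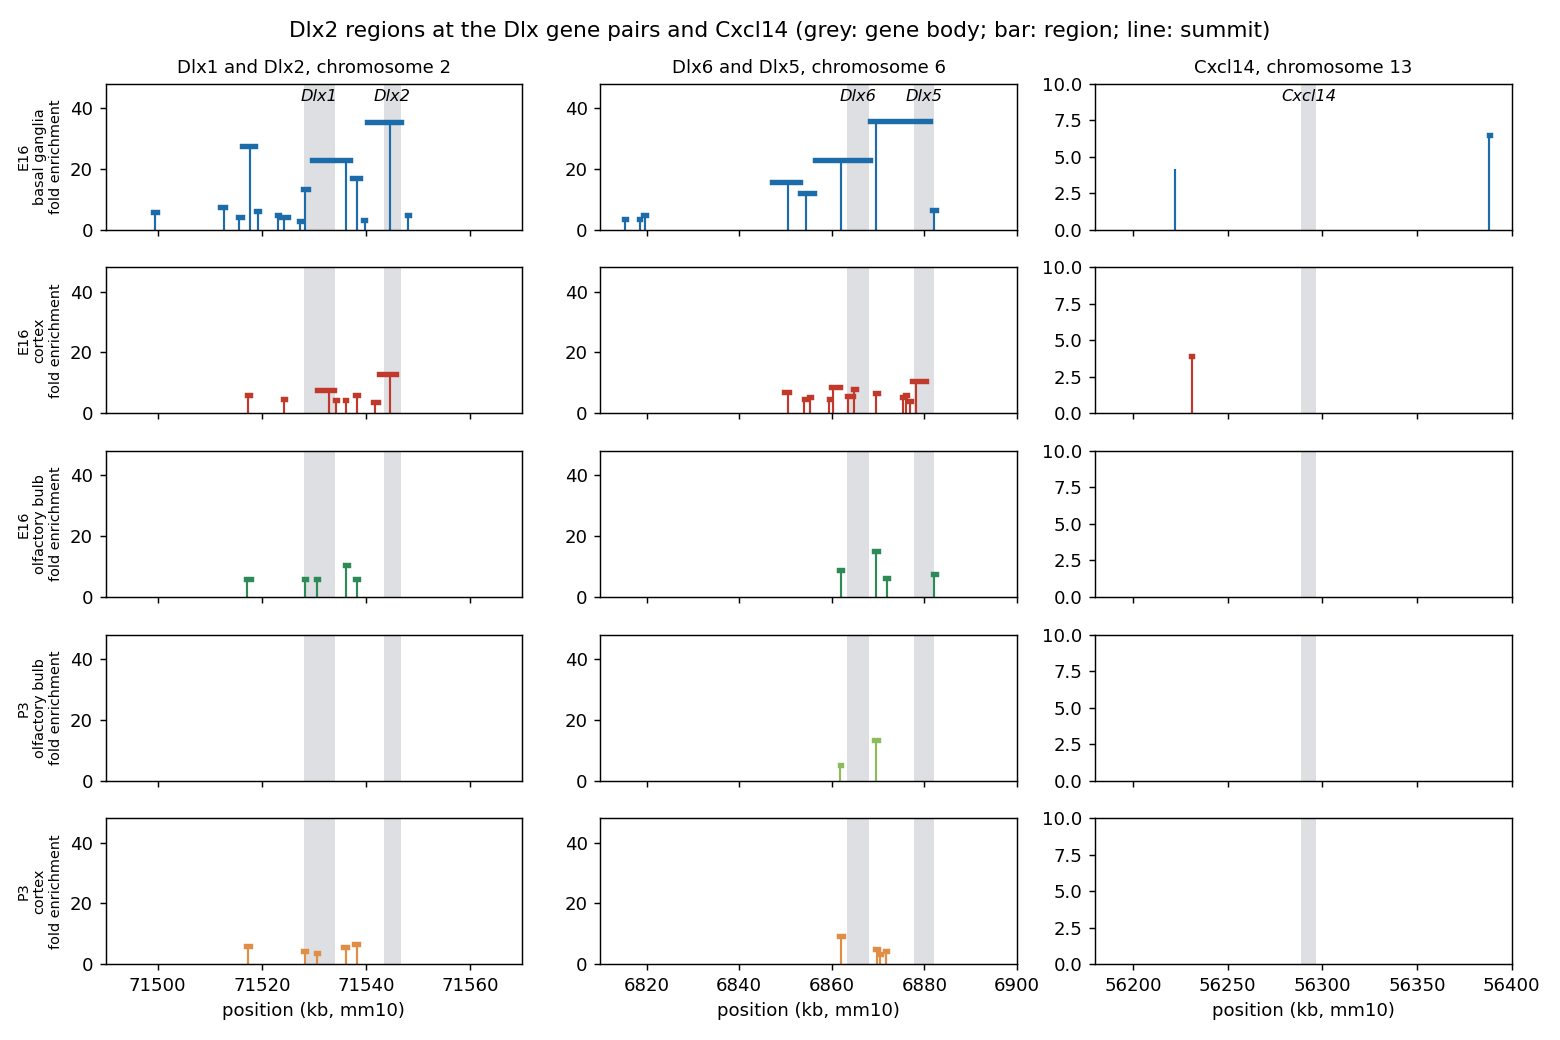
Dlx2 regions (horizontal bars) and their summits (vertical lines) at Dlx1 and Dlx2, at Dlx6 and Dlx5 and at Cxcl14, with position in kb on the x axis, fold enrichment on the y axis, gene bodies in grey and 1 row per list. The regions at the Dlx genes reached 35.6 in the basal ganglia, while the 3 regions plotted around Cxcl14 lay between 3.91 and 6.45.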

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

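The tests of list strength, region width, duplicate reads, age and series given here were chosen only after the result was seen, while that of position outside genes was set beforehand.

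2 shares of the same location breakdown moved in opposite directions from E16 to P3 in the cortex and in the bulb, each with 1 library per group, and the differences were not tested. The share of summits outside genes was 5.05% and 35.7% in the E16 and P3 cortex but 39.4% and 35.1% in the E16 and P3 bulb, so that the changes of 30.6 and −4.37 percentage points differ by 34.98. The share within 1 kb of a gene boundary was 21.9% and 18.2% in the cortex and 10.9% and 15.4% in the bulb, with changes of −3.66 and 4.49 that differ by −8.15. The share outside genes moved mainly in the cortex, while the boundary share moved in both.

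The E16 cortex regions were mostly within genes such as Mex3a and Fam171a2 and rarely in the bulb or P3 lists. Weak calls near the threshold are not enough to produce the rarity. Of the 100 strongest E16 cortex regions, 2 were in the E16 bulb list, 2 in the P3 bulb list and 3 in the P3 cortex list. The position of these 100 was not examined. Wide regions alone do not account for the rarity in the E16 bulb list either, because 2.64% of the regions of at most 1 kb were in that list. With 145 cortex regions in that list in all, this share could only be low. Whether the narrow regions lay mostly within genes was not examined. A candidate explanation is signal over transcribed or GC-rich genes that does not depend on Dlx2 sites: 10.8% of E16 cortex regions outside genes (7.57 to 14.9) but 1.85% of those within genes (1.52 to 2.22) were in the E16 bulb list, and ubiquitous genes were occupied in 8 of 12 cases. Against the basal ganglia list the shares hardly differed (64.9% and 61.3%), the contrast in the bulb list would also arise if bulb libraries favored distal sites, and binding by Dlx2 in cortical tissue stays open because no input or control library was analysed here.

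The strongest P3 cortex regions, such as those at Sema6a, Smad2 and Grip1, were missing from the E16 basal ganglia list, which held 11 of the 50 strongest (22.0%), against 43 of the 50 strongest E16 bulb regions and 39 of the P3 bulb. Of the 50 strongest P3 cortex regions missing from the basal ganglia list, 32 were in an olfactory bulb list, where shifted lists gave up to 3. Since the bulb peak names mark removed duplicates, this argues against duplicate reads as the only source of these 32 calls. It does not test whether duplicates raised their rank in the P3 cortex list. A locus prone to artifact signal in both libraries would give the same overlap. All 32 were in the E16 bulb list, which argues against sites that appear only after E16, while a later gain within the cortex stays open. For the other 18, found in no bulb list, duplicate reads and sites of the P3 cortex cannot be told apart. Of the 50, 0 were in the E16 cortex list (upper limit 7.11%) and 23 in the P3 bulb list, which has its own naming pattern. A site type held by some library series may explain those 23 only if it spans more than 1 pattern. For the rest, a site type of the pattern that the E16 bulb and P3 cortex lists share stays open. Series and group cannot be told apart.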

How the results depend on the processing

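Leaving out regions wider than 1 kb, the E16 cortex list or the P3 cortex list was chosen after the results were seen, and the other alternatives were set before the data were examined. No paired analysis was possible because each group has 1 library, which also rules out leaving out a library within a group. Of 151 alternative values for the main results, 84 stayed within the interval of the reported value, or within 1.5 times a count, and 67 moved. The cause was not tested except where the alternative itself removes regions or narrows or widens a window.

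At a −log10 q of at least 10 the lists held 6070 (E16 basal ganglia), 2352 (E16 cortex), 810 (E16 bulb), 372 (P3 bulb) and 734 (P3 cortex) regions. The share of E16 cortex regions in the basal ganglia list (61.5%) was 57.7% at a −log10 q of at least 5, 59.6% at 10, 36.1% with overlap of 50% of both regions, 38.8% with summits at most 200 bp apart, 35.4% at equal list length and 35.5% without wide regions. For the E16 bulb in the basal ganglia list (72.7%) it was 69.9% at 10, 55.2% with the 50% overlap, 67.9% by summits, 30.1% at equal length and 60.8% without wide regions. For the E16 bulb in the E16 cortex list (8.52%) it was 3.70%, 6.24%, 7.08% and 0.545% under the same settings, wide regions aside. The P3 cortex share in the E16 cortex list (5.14%) was 2.86% at 10, 3.37% with the 50% overlap, 3.65% by summits, 0.545% at equal length and 4.24% without wide regions. The P3 bulb share in the E16 bulb list (71.5%) was 51.5% at equal length, and in the P3 cortex list (25.6%) 21.0% at 10, 22.5% with the 50% overlap and 16.2% at equal length. Equal length also changed an order, since the E16 bulb share in the basal ganglia list was then below the E16 cortex share. The 33 regions in all 5 lists became 4 at 10, 1 at equal length, 11 with the 50% overlap, 12 without wide regions, 96 without the E16 cortex list and 61 without the P3 cortex list.

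The share within 1 kb of a gene boundary in the E16 basal ganglia list (16.7%) was 15.5% at 5, 13.7% at 10, 14.7% at equal length and 15.6% without wide regions. In the E16 cortex (21.9%) it was 23.6% at 10, 27.2% at equal length and 20.5% without wide regions, and in the E16 bulb (10.9%) 9.01% at 10 and 8.86% at equal length. The basal ganglia share was above that of the P3 bulb (15.4%) in whole lists and below it at equal length. Within 2500 bp it was 29.4%, 41.2%, 18.0%, 21.8% and 25.6% for the E16 basal ganglia, E16 cortex, E16 bulb, P3 bulb and P3 cortex, and with protein-coding genes only 10.9%, 16.3%, 5.40%, 8.46% and 12.1%. Gene lists at the percentile of 95 numbered 7 in the E16 cortex and 4 with gene bodies extended by 50 kb. In the E16 bulb they numbered 8, against 5 at a −log10 q of 10, 5 within 5 kb of gene boundaries and 4 at equal length, and in the P3 bulb 5 against 2 within 5 kb. Near Cxcl14 the basal ganglia had 1 summit at 10 and 5 within 500 kb, the E16 cortex 0 at 5, 0 at 10 and 6 within 500 kb, and the E16 bulb, P3 bulb and P3 cortex 1 each within 500 kb. Of 510 alternative percentiles of the gene lists, 475 stayed on their side of 95, 23 fell below it and 12 rose above it. Counting each summit changed no count, since a region has 1 summit. The motif alternatives and distances to transcription starts were not run. Depth is unknown, so its effect on list length was not separated from tissue and age.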

Other observations

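The tests on small nuclear RNA genes were chosen after the result was seen, except that of list length, which was set before its value was known.

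Genes for small nuclear and nucleolar RNAs, which are short noncoding genes of the splicing and RNA-processing machinery, carried some of the strongest regions of the bulb and P3 cortex lists. The spliceosomal gene Rnu1a1 (chromosome 11, 87422867 to 87423030) had a fold enrichment of 14.7 in the P3 bulb, 12.2 in the P3 cortex, 6.77 in the E16 bulb and 7.71 in the basal ganglia. Rnu2-10 had 13.02, 13.6, 6.42 and 6.75 in the same order, Rnu3b2 17.1, 12.9, 4.56 and 5.04, and Rnu11, a minor spliceosome gene, 10.2, 13.8, 5.72 and 9.97. At Rnu3b4 the P3 bulb, P3 cortex and E16 bulb lists had regions (10.2, 13.02 and 10.2) and the basal ganglia list had none. None of these genes had a region in the E16 cortex list. Within 1 kb of 1004 annotated small nuclear RNA genes lay 40 summits of the P3 cortex list, 31 of the P3 bulb, 29 of the E16 bulb, 32 of the basal ganglia and 2 of the E16 cortex. Among the 100 strongest regions of each list these were 23, 20, 7, 0 and 0. For the whole lists, shifted positions gave means of 1.68, 0.636, 1.34, 11.8 and 5.19 in the same order. The maxima were 7, 4, 6, 25 and 14.

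Chance position does not account for the 31 summits of the P3 bulb list, since shifted lists gave a mean of 0.636 and a maximum of 4. Reads that match several near-identical gene copies stay open: 0 of these 31 regions were in the E16 cortex list (upper limit 11.2%), but that list held 8.99% of all P3 bulb regions (7.02 to 11.3), so this absence does not set them apart. The basal ganglia list held 74.2% of them, at a median fold enrichment of 4.18 for its summits near such genes against 4.55 elsewhere, so its greater length may or may not be what puts them low in its ranking. Whether the signal at these genes comes from Dlx2, from another protein met by the antibody or from open chromatin was not tested.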
